A study of Mus musculus with 6 samples.

How the data were processed

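NK1.1+ cells from the spleens of RAG-deficient mice were sorted by the submitters into 3 subsets by CD27 and CD11b, and RNA of 2 samples per subset was hybridised to Affymetrix mouse whole-genome expression arrays, per the labels. The deposited value table holds log2 expression values for 45101 probe sets on 6 arrays, with the log2 scale read from the range of the values. The values were made with RMA, per the submitters' processing notes, and the RMA version and chip definition are not given in the sources used here. RMA corrects background, equalises the distribution of values between arrays and summarises the probes of a probe set, so a change shared by most genes would be removed, and differences of dim genes are compressed toward 0. Scanner files were not used here. Array medians lay between 5.26 and 5.35, with minima near 2.60 and maxima up to 14.72. For arrays, the number of samples limits the precision.

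Of the probe sets, 64 were controls and were left out. Gene names came from the array annotation table: 34945 of the remaining 45037 probe sets had 1 gene symbol, 932 had several and 9160 had none, and no gene was named from a probe set with several symbols. The gene identifiers of 34741 of the probe sets with 1 symbol were found in the RefSeq gene table, and 0 symbols needed updating. Each of 18193 genes was represented by the probe set with the highest mean over the 6 arrays, a choice that concerned the 9010 genes with more than 1. No genome coordinates were used. The background level of 6.46 was the 95th percentile of the 6-array means of 50 measured genes of other tissues, and 8620 genes lay above it in at least 1 subset.

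Samples were grouped by their titles. The main model was a limma fit (limma 3.58.1 in R 4.3.3) with 1 mean per subset over all 6 arrays, with 3 residual and 4.93 prior degrees of freedom, and moderated statistics adjusted by the Benjamini-Hochberg method over all genes. A gene was called at an adjusted p under 0.05. The 3 pairwise comparisons, an F test over the subsets and the difference between the 2 steps came from this fit. Named genes were the 10 with the largest positive and the 10 with the largest negative difference among called genes whose arrays did not overlap, with all that passed named where fewer did, plus the sorting markers and members of the gene lists with their calls. There were 40 genes named by size. Of these, Trgv4 and Myb lie on probe sets whose names mark possible matches to transcripts of other genes. For the 9 gene and comparison pairs with another probe set above background, 0 had a probe set in the opposite direction and 0 had a difference under 0.5 times as large on it.

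There were 16 function lists (cell cycle, cytotoxic granule and death ligands, NK cell surface receptors, homing and adhesion, transcription factors, cytokine receptors, secreted cytokines and chemokines, activating receptor signalling, cytosolic ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, glycolysis, cholesterol synthesis, type I interferon response, immediate early and heat shock, and apoptosis) and 10 marker lists of other cell types (T cell, B cell, monocyte and macrophage, neutrophil, dendritic cell, mast cell and basophil, erythroid, megakaryocyte and platelet, other innate lymphoid cell, and stroma). They were tested with camera at an inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 26 lists of a comparison. Of the 10, 6 and 8 lists called in the first, second and outer comparison, 0 were called with an estimated correlation. That test rests on the 3 residual degrees of freedom of the fit, while the test with a fixed correlation does not. The homing list lost its call in the first comparison (camera adjusted p = 0.0213 to 0.484) at an estimated correlation of -0.0009. A lost call therefore does not show that correlation between genes explains it. The groups, tests, lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says otherwise.

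The statistics were tested on simulated data with 200 changed genes in each of 5 runs over 18193 genes. The changed genes were drawn from those with a mean at or above the median, 100 changed 2-fold and 100 changed 4-fold. With each gene's own estimated spread, 80.4% of genes changed 2-fold and 100% of those changed 4-fold were recovered in the first comparison, 83.2% and 99.8% in the second and 81.2% and 99.6% in the outer one, and 10.2%, 8.6% and 9.0% of the calls were false. With spreads drawn from the fitted prior, recovery was 49.6% and 97.8%, 47.4% and 97.8%, and 53.2% and 97.2%, and 5.0%, 4.8% and 4.9% of calls were false. The false share thus exceeded the 5% aimed at where the simulated spreads were the estimated ones. The recovery shares do not hold for dim genes, which were not among the changed ones. With fewer changed genes the adjusted threshold is stricter. Recovery of 2-fold changes may thus be lower in the first comparison, where 22 genes were called in the arrays. The simulated arrays also held no on and off division, which is described in the Results. A list shifted by 0.5 on the log2 scale was called in all 5 runs of every comparison, and at most 1 of 125 tests of other lists was called. The simulated genes were drawn independently of each other, so these runs do not show how often camera calls unchanged lists of correlated genes. In the arrays the estimated correlation reached 0.77 for monocyte and macrophage markers and 0.75 for cell cycle genes.

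Alternatives were the replicate number as a block, genes with low means left out, a further quantile normalization, arrays centred on their medians, 32 added on the linear scale, the mean of a gene's probe sets, every probe set tested, the 2 compared subsets fitted alone, a prior spread with a trend, a minimum of 2-fold and each array left out in turn. The fit with the on and off arrays as a block was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 from tables made with pandas 2.3.3.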

Results

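Gene expression was measured in natural killer (NK) cells sorted from the spleens of RAG-deficient mice, which cannot rearrange antigen receptor genes and so lack mature T and B cells. NK1.1+ cells were separated by flow cytometry into cells with CD27 alone (CD27+CD11b-), with both markers (CD27+CD11b+) and with CD11b alone (CD27-CD11b+). CD27 is a co-stimulatory receptor of the tumour necrosis factor receptor family, and CD11b, encoded by Itgam, is the alpha chain of the integrin Mac-1. The subsets are commonly placed in this order as successive stages of NK cell maturation. Each subset was profiled on 2 arrays, 6 arrays in all, and the series design describes the 2 as independent replicates. Nothing in the labels says that they came from separate animals, so p-values measure the spread between these samples, which may be technical, and the number of arrays limits the precision. Array medians lay between 5.26 and 5.35 on the log2 scale. All means below are log2 values ± SD over n = 2 arrays per subset, and differences are log2 differences with the standard error (SE) of the limma fit. Genes with a mean under 6.46, the level of genes of other tissues, are called near background, because the value table holds no detection calls.

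The sorting markers were read first. Cd27 was 8.41 ± 0.53 in CD27+CD11b-, 8.57 ± 0.50 in CD27+CD11b+ and 6.71 ± 0.35 in CD27-CD11b+. Itgam was 6.13 ± 0.34, 8.35 ± 0.48 and 9.69 ± 0.34 in the same order. Ptprc, the pan-leukocyte marker CD45, stayed between 13.47 and 13.71 in all 6 arrays by the probe set used. A second probe set ranged from 9.59 in CD27-CD11b+ replicate 1 to 11.50. The sort description of CD27-CD11b+ replicate 1 reads as the CD27+CD11b- gate while its title reads CD11b+ CD27-, and the array was grouped by its title. Its Cd27 value of 6.96 and Itgam value of 9.93 lay beside those of CD27-CD11b+ replicate 2, 6.47 and 9.44. Klrb1c, which encodes NK1.1, was not named because its probe set matches several genes.

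A second division of the arrays crossed the subsets. A group of 3 unnamed probe sets averaged between 12.57 and 12.81 in CD27+CD11b- replicate 2, CD27+CD11b+ replicate 2 and CD27-CD11b+ replicate 1, called here the on arrays, and between 4.33 and 4.47 in the other 3, called the off arrays. Each set of 3 arrays holds 1 array of every subset, so each comparison could be made within both and in a fit with this division as a block, which leaves the differences as they are and changes their spread. With 1 array left out, the division enters the comparisons of that array's subset. The division was read from the data, and the blocked fit was chosen after seeing them, so its adjusted p-values may be too small and its counts too high. Transcripts of monocytes and macrophages followed it: the mean of 20 such genes was 5.84, 6.65 and 6.55 in the off arrays of CD27+CD11b-, CD27+CD11b+ and CD27-CD11b+, and 7.21, 7.57 and 7.41 in the on arrays. The mean of 35 cell cycle genes was 8.95, 8.45 and 7.29 in the off arrays and 7.84, 7.41 and 7.13 in the on arrays. The first principal component, with 49.3% of the variance, ordered the subsets, and the second, with 24.1%, separated the 2 arrays of CD27+CD11b- and the 2 of CD27+CD11b+ from each other.

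**Figure D1:**
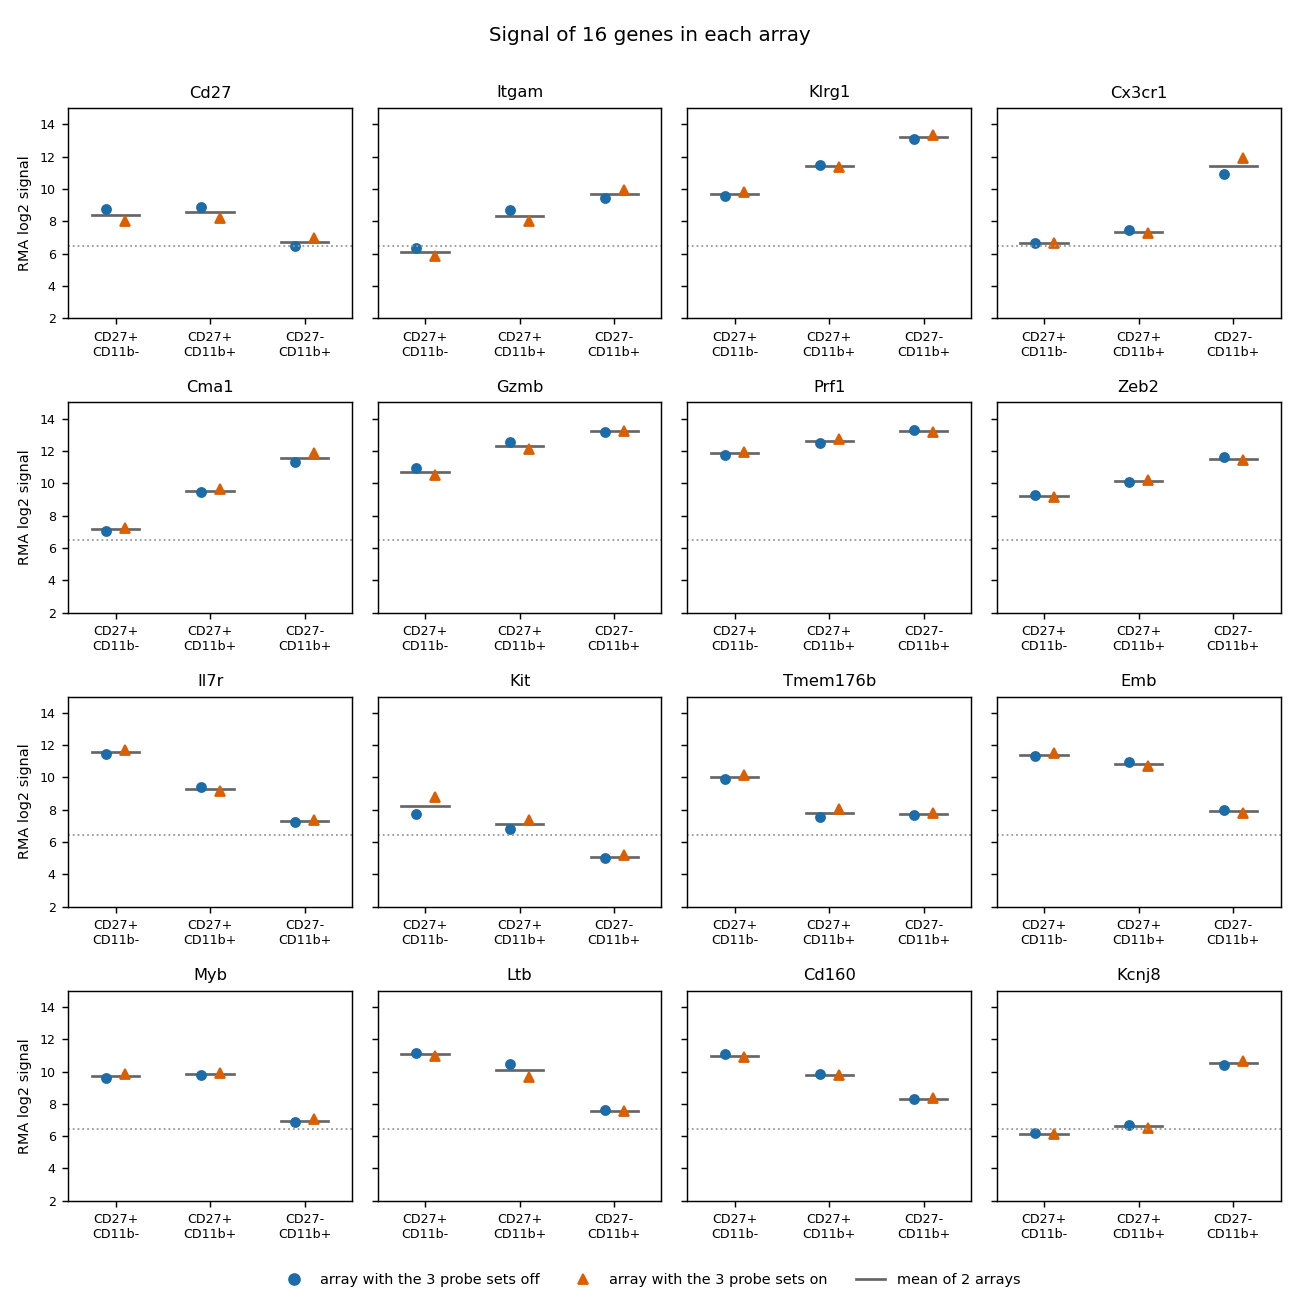
Log2 expression (vertical axis) of 16 genes in the 3 subsets (horizontal axis), with 1 mark per array, circles for the off arrays and triangles for the on arrays, a line at the mean of 2 arrays and a dotted line at the background level of 6.46. Cma1, Klrg1 and Zeb2 climb from CD27+CD11b- to CD27-CD11b+, Il7r and Cd160 descend, and Kcnj8 stands at 6.16, 6.60 and 10.54.

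CD27+CD11b+ cells were compared with CD27+CD11b- cells to find the transcripts that accompany the gain of CD11b among CD27+ cells. Effector and inhibitory genes were among those that rose: Gzmb, the death-inducing protease granzyme B, went from 10.71 ± 0.32 to 12.33 ± 0.31, a 3.07-fold change, and Klrg1, an inhibitory receptor that binds cadherins, from 9.71 ± 0.20 to 11.43 ± 0.06. Cma1, a chymase best known from mast cell granules, rose 5.24-fold, from 7.16 ± 0.13 to 9.55 ± 0.10. A survival receptor and an antigen receptor locus gave the largest falls: Il7r, the alpha chain of the interleukin-7 receptor, went from 11.59 ± 0.16 to 9.26 ± 0.18, and Trgv1, a variable segment of the T cell receptor gamma locus, fell 8.84-fold, from 9.81 ± 0.04 to 6.66 ± 0.44. In all, 22 of 18193 genes passed an adjusted p of 0.05 in limma, 6 higher and 16 lower in CD27+CD11b+. An unadjusted p under 0.05 was reached by 690.

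The 6 that rose were Cma1 (difference 2.39, SE 0.20, adjusted p = 0.00993), the sorting marker Itgam (2.22, SE 0.28, adjusted p = 0.0407), Serpinb9b of the intracellular serpin family (1.95), Klrg1 (1.72, adjusted p = 0.0171), Gzmb (1.62, adjusted p = 0.0484) and Cmklr1, the chemerin receptor (1.42). The 10 largest falls were in Trgv1 (-3.14, SE 0.21, adjusted p = 0.00484), Il7r (-2.32, SE 0.17, adjusted p = 0.00484), Tmem176b (-2.23), the scavenger receptor family member Cd163l1 (-2.10), the acid phosphatase Acpp (-1.98), Trgv4 of the same locus as Trgv1 (-1.97), Psd2 (-1.94), Tnfrsf25, a death domain receptor (-1.93), the phosphoinositide phosphatase Inpp4b (-1.79) and Tmem176a (-1.75). Trgv4 and Psd2 were near background in both subsets, at 6.37 ± 0.25 and 6.34 ± 0.46 in CD27+CD11b-, so no fold change is given for them. Measured from the background level, Itgam rose at least 3.70-fold. Cd163l1, Tnfrsf25 and Inpp4b, near background in CD27+CD11b+, fell at least 2.82-fold, 2.42-fold and 1.45-fold.

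Among the marker list of other innate lymphoid cells, 3 of 9 measured members fell and 6 did not pass, and 5 fell adjusted over the list alone. Il7r, Tmem176a and Tmem176b were those that fell over all genes, and the list's median difference was -1.16 (-0.89 in the off and -1.43 in the on arrays, the order used for all later pairs of medians). The list's median was -1.70 without CD27+CD11b- replicate 1 and -0.61 without CD27+CD11b- replicate 2. Its camera call (adjusted p = 1.93e-10) was lost at adjusted p = 0.186 with an estimated correlation. That correlation was only 0.021, and the test with it rests on 3 residual degrees of freedom, as for every list below. Of 26 granule genes and death ligands, Gzmb rose and 25 did not pass, with 2 rising and 1 falling adjusted over the list alone. The list's camera adjusted p was 0.00185, against adjusted p = 0.560 with an estimated correlation, and its medians were 0.16 and 0.18 in the off and on arrays. Within the 29 NK cell surface receptors, Klrg1 rose, Cd160 and Cd200r1 fell by 1.19 and 1.61 on the log2 scale, Cd200r1 to near background, and 26 did not pass (2 rose and 4 fell adjusted over the list alone). Ikzf2, the Ikaros family factor Helios, alone passed among 44 transcription factors, at -1.67 (SE 0.18, adjusted p = 0.0217), and 2 rose and 7 fell adjusted over the list alone. In the blocked fit 3 of these factors fell over all genes. Cd22, an inhibitory lectin of B cells, fell by 1.53 on the log2 scale and was the only B cell marker of 13 to pass over all genes or adjusted over the list alone. That list's camera adjusted p was 7.25e-04, and adjusted p = 0.484 with an estimated correlation (medians -0.23 in the off and -0.14 in the on arrays).

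None of the 35 cell cycle genes passed over all genes or adjusted over the list alone, although 33 differences were negative, and in the blocked fit 1 fell over all genes and 2 adjusted over the list alone. The list's median was -0.49 (-0.49 in the off and -0.45 in the on arrays) with camera adjusted p = 8.49e-06, and adjusted p = 0.778 with an estimated correlation. The 20 monocyte and macrophage markers had a median of 0.64 (0.90 in the off and 0.36 in the on arrays), 19 of them positive and 0 past the test either way (0 over all genes and 14 rising adjusted over the list alone in the blocked fit), with camera adjusted p = 2.51e-05 and adjusted p = 0.778 with an estimated correlation. The 24 immediate early and heat shock genes also had 0 members past the test either way, a median of 0.28 (0.23 and 0.22) and camera adjusted p = 0.00104, against adjusted p = 0.778 with an estimated correlation. Without CD27+CD11b- replicate 1 these 3 medians became 0.087, -0.051 and 0.0011. Leaving out that off array lets the on and off division enter the difference. The median gaps, on minus off, of these lists in CD27+CD11b- were -1.21, 1.63 and 0.54. These turns therefore mix the division with the step. Of 28 activating receptor signalling genes, 0 passed over all genes and 1 rose adjusted over the list alone (medians 0.16 and 0.13, camera adjusted p = 0.00185, adjusted p = 0.765 with an estimated correlation). Among 26 homing and adhesion genes only Itgam, the sorting marker, rose, and 3 rose and 1 fell adjusted over the list alone (medians 0.23 and 0.12, camera adjusted p = 0.0213, adjusted p = 0.484 with an estimated correlation). The homing median was 0.23 with all arrays and 0.016 without CD27+CD11b+ replicate 1. Of 19 apoptosis regulators and of 8 megakaryocyte markers, 0 passed over all genes and 1 of each rose adjusted over the list alone. The apoptosis list had medians of 0.05 and 0.08 (camera adjusted p = 0.0390, adjusted p = 0.560 with an estimated correlation) and the megakaryocyte list 0.19 and 0.18 (camera adjusted p = 0.0405, adjusted p = 0.560 with an estimated correlation). The megakaryocyte median was 0.32 without CD27+CD11b+ replicate 1 and -0.017 without CD27+CD11b+ replicate 2. The remaining 16 of 26 lists were not called.

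With the on and off arrays as a block 58 genes passed, 11 higher and 47 lower, and the differences within the off and within the on arrays correlated at 0.424 across all genes, with 53 genes at least 2-fold in both in the same direction and 0 in opposite directions. The count became 4 without CD27+CD11b+ replicate 1, 5 without CD27+CD11b+ replicate 2, 10 without CD27+CD11b- replicate 2 and 12 without either CD27-CD11b+ array, and it was 0 after adding 32 to the linear values.

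CD27-CD11b+ cells were compared with CD27+CD11b+ cells to find the transcripts that accompany the loss of CD27. Cx3cr1, the fractalkine receptor, rose 16.9-fold, from 7.36 ± 0.14 to 11.44 ± 0.70, and Kcnj8, a pore subunit of ATP-sensitive potassium channels, 15.4-fold, from 6.60 ± 0.17 to 10.54 ± 0.16. The transcription factors Zeb2 and Prdm1, both regulators of effector lymphocyte maturation, rose by 1.38 and 1.47, and S1pr5, a sphingosine-1-phosphate receptor used for egress from lymphoid organs, by 1.58. Myb, a transcription factor of progenitor cells, fell 7.38-fold, from 9.85 ± 0.10 to 6.96 ± 0.11, and Ltb, the membrane-anchoring lymphotoxin beta chain, 5.60-fold, from 10.07 ± 0.60 to 7.58 ± 0.03. Cd27, the sorting marker, differed by -1.86 (SE 0.32) and did not pass (adjusted p = 0.0772, and 0.0228 in the blocked fit). The test passed 54 genes, 31 higher and 23 lower in CD27-CD11b+. An unadjusted p under 0.05 was reached by 2027.

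The 10 largest rises were in Cx3cr1 (4.08, SE 0.29, adjusted p = 0.00238), Kcnj8 (3.94, SE 0.16, adjusted p = 1.80e-04), the glutathione peroxidase family member Gpx8 (2.89), the chromatin remodelling subunit Smarcd3 (2.82), the mitochondrial topoisomerase Top1mt (2.69), the aspartic protease Cym (2.35), the platelet glycoprotein subunit Gp1bb (2.30, SE 0.32, adjusted p = 0.0417), Denn2b (2.27), Rhpn1 (2.18) and Cma1 (2.02, SE 0.20, adjusted p = 0.0125). The 10 largest falls were in the membrane glycoprotein Emb (-2.94, SE 0.17, adjusted p = 7.59e-04), Myb (-2.88, SE 0.16, adjusted p = 7.59e-04), Ltb (-2.49), Thy1, the surface glycoprotein CD90 (-2.19), Kbtbd11 (-2.12), Il7r (-1.96, SE 0.17, adjusted p = 0.00537), the chemokine receptor Cxcr3 (-1.84), the desmosomal protein Dsp (-1.79), Hook1 (-1.70) and the class II accessory chain H2-Oa (-1.69). Klrg1 rose again, by 1.80, to 13.23 ± 0.21 in CD27-CD11b+. Of these genes, Gpx8, Smarcd3, Top1mt, Cym, Gp1bb and Rhpn1 were near background in CD27+CD11b+ and rose at least 2.13-fold, 3.45-fold, 4.15-fold, 4.26-fold, 4.07-fold and 1.60-fold from that level. Hook1 and H2-Oa fell to near background, at least 2.16-fold and 2.20-fold. Dsp, at 6.46 in CD27+CD11b+ and 4.67 in CD27-CD11b+, is given no fold change.

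Of 26 homing and adhesion genes, Cx3cr1 and S1pr5 rose, Ccr2 (-1.03) and Cxcr3 fell and 22 did not pass, and 3 rose and 4 fell adjusted over the list alone. Within the 29 surface receptors Klrg1 rose, Cd160 (-1.47), Slamf6 (-1.31, to near background) and Crtam (-1.61) fell and 25 did not pass, and 5 rose and 3 fell adjusted over the list alone. Zeb2 and Prdm1 rose and Myb fell among 44 transcription factors, and 6 rose and 3 fell adjusted over the list alone. Ltb alone passed among 16 secreted cytokines and chemokines, and 4 rose and 4 fell adjusted over the list alone (2 rose and 2 fell over all genes in the blocked fit). None of the 19 type I interferon response genes passed over all genes and 9 fell adjusted over the list alone, among them Ifit1 at -1.22 and Usp18 at -0.97. In the blocked fit 6 fell over all genes and 1 rose and 9 fell adjusted over the list alone. That list's median was -0.34 (-0.63 in the off and -0.50 in the on arrays), with camera adjusted p = 7.97e-09 and adjusted p = 0.257 with an estimated correlation. Among 10 T cell markers Thy1 fell and 3 fell adjusted over the list alone, with camera adjusted p = 6.29e-04 and adjusted p = 0.623 with an estimated correlation (medians -0.24 and -0.19). Il7r was the member of the 9 markers of other innate lymphoid cells that fell, 2 fell adjusted over the list alone, and the list's camera adjusted p was 0.0119, against adjusted p = 0.623 with an estimated correlation (median -0.06, with -0.19 and -0.21, and 0.0006 without CD27+CD11b+ replicate 2).

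Cell cycle genes had a median of -0.88, with 31 of 35 differences negative and 0 past the test over all genes or adjusted over the list alone, against 5 and 18 that fell in the blocked fit. Their median was -0.20 without CD27+CD11b+ replicate 1 and -1.49 without CD27+CD11b+ replicate 2. It was -1.24 in the off arrays and -0.27 in the on arrays, with camera adjusted p = 6.09e-07 and adjusted p = 0.815 with an estimated correlation. Neither the 29 ribosome biogenesis genes nor the 27 cytosolic ribosomal proteins had a member past the test either way. The biogenesis list had a median of -0.28 (-0.35 and -0.16, and -0.38 to -0.10 with 1 array left out, camera adjusted p = 2.51e-06, adjusted p = 0.815 with an estimated correlation) and the ribosomal protein list a median of -0.15 (-0.23 and -0.02, and -0.29 to -0.03 with 1 array left out, camera adjusted p = 0.00678, adjusted p = 0.815 with an estimated correlation). The other 20 lists were not called, and the monocyte and macrophage markers had a median of -0.17 (-0.59 to 0.40 with 1 array left out) with 0 of 20 past the test.

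With the on and off arrays as a block 296 genes passed, 163 higher and 133 lower, and the differences within the off and within the on arrays correlated at 0.365 across all genes, with 97 genes at least 2-fold in both in the same direction and 3 in opposite directions. The count became 6 without CD27-CD11b+ replicate 1, 25 without CD27-CD11b+ replicate 2, 13 without CD27+CD11b+ replicate 1 and 11 without CD27+CD11b+ replicate 2, and it was 11 after adding 32 to the linear values.

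CD27-CD11b+ cells were then set against CD27+CD11b- cells, the first and last subsets of the order. Genes of the killing machinery were among those that rose: Gzmb by 2.50, to 13.21 ± 0.03, Prf1, the pore-forming protein perforin, by 1.38, to 13.23 ± 0.11, and Ctsc, the protease that activates granzymes, by 0.78. Tbx21 (10.61 ± 0.26 to 11.71 ± 0.03), Zeb2 (2.30) and Prdm1 (2.34), transcription factors of effector lymphocytes, rose as well. Receptors for growth and survival signals were among those that fell: Il7r 19.5-fold, from 11.59 ± 0.16 to 7.30 ± 0.12, and Kit, the stem cell factor receptor, at least 3.46-fold, from 8.25 ± 0.77 to 5.10 ± 0.13. Mki67, the proliferation marker Ki-67, fell by 2.76 on the log2 scale, from 10.85 ± 0.89 to 8.09 ± 0.64. A total of 617 genes passed, 408 higher and 209 lower in CD27-CD11b+, of which 374 differed at least 2-fold, 215 higher and 159 lower, and 84 were near background in both subsets.

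The 10 largest rises were in Cx3cr1 (4.79, SE 0.29, 27.6-fold, adjusted p = 2.92e-04), Cma1 (4.41, SE 0.20, 21.3-fold), Kcnj8 (4.38, SE 0.16, adjusted p = 6.26e-05), Itgam (3.56), Klrg1 (3.52, SE 0.17, adjusted p = 1.12e-04), Gp1bb (3.51), Gpx8 (3.49), the ectonucleotidase Entpd1, also called CD39 (3.21), Smarcd3 (3.20) and Serpinb9b (3.08). The 10 largest falls were in Il7r (-4.29, SE 0.17, adjusted p = 6.26e-05), Trgv1 (-4.28, SE 0.21, adjusted p = 1.12e-04), Emb (-3.52), Ltb (-3.48), the inhibitory receptor Ctla4 (-3.45, SE 0.42), the sialyltransferase St6galnac3 (-3.42, SE 0.62, adjusted p = 0.0297), the oxysterol receptor Gpr183 (-3.31), Acpp (-3.30), Kit (-3.16, SE 0.34, adjusted p = 0.00402) and the aryl hydrocarbon receptor Ahr (-2.76, SE 0.50, adjusted p = 0.0295). St6galnac3 was 4.90 ± 1.67 in CD27-CD11b+, the widest spread among these genes. It was 3.73 in replicate 1, at least 2 log2 units below every other array, and 6.08 in replicate 2. From the background level Kcnj8 rose at least 17.0-fold, Itgam 9.36-fold, Gp1bb 4.07-fold, Gpx8 2.13-fold, Entpd1 3.64-fold and Smarcd3 3.45-fold. Trgv1 fell at least 10.2-fold, Acpp 5.12-fold, Gpr183 7.07-fold, Ctla4 3.81-fold and St6galnac3 3.63-fold. Cd27 itself fell by 1.70 on the log2 scale (SE 0.32, adjusted p = 0.0325).

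Of 26 granule genes and death ligands, Gzmb, Prf1, Ctsc and the cathepsin inhibitor Cst7 (0.87) rose, Gzmm (-1.44) and Tnfsf10, the death ligand TRAIL (-1.11), fell and 20 did not pass, with 9 rising and 3 falling adjusted over the list alone. Among 44 transcription factors 7 rose and 3 fell, with 9 and 9 adjusted over the list alone: Irf8 (1.12), Klf2 (1.52), Klf3 (0.94) and Gfi1 (0.82) joined Tbx21, Zeb2 and Prdm1, and Klf4 (-2.43), Ikzf2 (-2.39) and Myb (-2.75) fell. Homing genes divided into Cx3cr1, S1pr5 (2.54) and the sorting marker Itgam, which rose, and Ccr2 (-0.81), Cxcr3 (-2.10), Cxcr6 (-2.34) and Gpr183, which fell, and 19 of 26 did not pass (7 rose and 4 fell adjusted over the list alone). Chemokines and cytokines changed in both directions, with Ccl3 (1.54), Ccl4 (1.74), Ccl9 (1.79) and Osm (1.44) rising and Tnf (-0.86), Lta (5.99 to 4.89), Ltb, Il2 (-1.12) and Lif (-1.28) falling among 16 measured (5 rose and 8 fell adjusted over the list alone). Lta and Il2 were near background in every subset. Of 29 surface receptors, Klrc2 (1.05) and Klrg1 rose, Cd160 (-2.66), Slamf6 (-2.02), Cd200r1 (-1.44) and Crtam (-1.91) fell and 23 did not pass (8 rose and 4 fell adjusted over the list alone). Among 28 cytokine receptors Il10ra (1.21) rose, Il2ra (-1.93), Il7r, Kit and the sorting marker Cd27 fell and 23 did not pass (5 rose and 4 fell adjusted over the list alone). These 6 lists were not called by camera, the granule list at adjusted p = 0.0568.

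Cell cycle and interferon genes were among those that fell. Of 35 cell cycle genes, Mki67 and the replication licensing factor Cdc6 (-2.13) fell and 33 did not pass, and 15 fell adjusted over the list alone. Their median was -1.33 (-1.93 in the off and -0.61 in the on arrays, and -0.59 and -2.17 without CD27+CD11b- replicate 1 and 2), with camera adjusted p = 3.04e-10 and adjusted p = 0.717 with an estimated correlation, and 18 fell over all genes in the blocked fit. Among 19 type I interferon response genes Ifit1 (-1.44), Ifit3 (-0.99), Oas1a (-0.87), Oas3 (-1.05) and Rtp4 (-1.09) fell and 14 did not pass, with 1 rising and 7 falling adjusted over the list alone. That list's median was -0.43 (-0.40 and -0.57), with camera adjusted p = 1.06e-04 and adjusted p = 0.348 with an estimated correlation. Tsr1, a ribosome assembly factor, fell by 1.08 on the log2 scale and alone passed among 29 ribosome biogenesis genes, over all genes and adjusted over the list alone, where 4 and 6 fell in the blocked fit (medians -0.38 and -0.18, camera adjusted p = 3.27e-04, adjusted p = 0.717 with an estimated correlation). None of the 27 cytosolic ribosomal proteins passed either way (medians -0.30 and -0.12, camera adjusted p = 0.00361, adjusted p = 0.717 with an estimated correlation). With 1 array left out the median ranged from -0.31 to -0.07 for these proteins and from -0.43 to -0.05 for ribosome biogenesis. Of 28 activating receptor signalling genes, the Fc receptor gamma chain Fcer1g (1.30), the kinase Txk (1.06) and Rasgrp2 (0.92) rose, Rasgrp1 (-0.89) and the CD3 delta chain Cd3d (-2.38) fell and 23 did not pass, with 6 rising and 4 falling adjusted over the list alone (medians 0.23 and 0.43, camera adjusted p = 0.0303, adjusted p = 0.717 with an estimated correlation).

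Among the lists of other cell types, all 5 markers of other innate lymphoid cells above background in CD27+CD11b- fell, Il7r, Kit, Cxcr6, Tmem176a (-1.79) and Tmem176b (-2.29), and 4 of the 9 did not pass, with the same counts adjusted over the list alone. The list's median was -1.79 (-1.57 and -1.65), with camera adjusted p = 2.01e-07 and adjusted p = 0.318 with an estimated correlation. Of 10 T cell markers Cd3d, Cd28 (-2.13) and Thy1 (-1.98) fell, 4 adjusted over the list alone (medians -0.51 and -0.14, camera adjusted p = 0.00197, adjusted p = 0.575 with an estimated correlation). Of 13 B cell markers the immunoglobulin mu locus Ighm (-0.84) and Cd22 (-2.21) fell, also adjusted over the list alone (medians -0.35 and -0.18, camera adjusted p = 0.00262, adjusted p = 0.575 with an estimated correlation). The 20 monocyte and macrophage markers had a median of 0.46 (0.83 in the off and 0.05 in the on arrays, and -0.26 to 1.33 with 1 array left out) with 0 past the test either way, and 5 rose in the blocked fit. Of 9 mast cell and basophil markers Cma1 rose, of 8 megakaryocyte markers Gp1bb, and of 12 erythroid markers the transferrin receptor Tfrc fell by 0.78 on the log2 scale (3 fell adjusted over the list alone). None of the 16 neutrophil, 14 dendritic cell and 11 stromal markers passed either way. In the blocked fit 2 neutrophil markers rose and 1 fell over all genes (4 and 2 adjusted over the list alone), and 1 dendritic cell and 1 stromal marker fell. Of the list members named for this comparison, Cd3d, Cd22, Cdc6, Gzmm, Cxcr6, Slamf6, Cd200r1, Tnf and Ifit1 fell to near background, Ccl9 and Msmo1 rose from it, and Klrc2, Il2ra, Lif and Oas3 were near it in both subsets.

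Hk1 (1.23) and Pfkl (1.01), both glycolytic enzymes, rose among 14 measured (5 rose and 1 fell adjusted over the list alone, and 4 rose and 1 fell over all genes in the blocked fit). The sterol oxidase Msmo1 (0.95) rose among 16 genes of cholesterol synthesis (1 adjusted over the list alone), and none of the 30 oxidative phosphorylation genes passed either way, with a median of 0.14. Pmaip1, the pro-apoptotic protein Noxa, rose by 1.78 among 19 apoptosis regulators (3 adjusted over the list alone), and the immediate early gene Ier2 by 1.04 among 24 (3 rose and 1 fell adjusted over the list alone, and 6 rose and 1 fell over all genes in the blocked fit). None of these 5 lists was called by camera. The median and the mean difference had opposite signs for glycolysis (-0.01 and 0.18), transcription factors (0.13 and -0.03), dendritic cell markers (0.01 and -0.04) and mast cell markers (-0.11 and 0.36), and the camera direction of the neutrophil, erythroid, mast cell and transcription factor lists, all uncalled, was opposite to their mean.

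The blocked fit passed 1480 genes, 965 higher and 515 lower, and the differences within the off and within the on arrays correlated at 0.657 across all genes, with 344 genes at least 2-fold in both in the same direction and 2 in opposite directions. The count became 84 without CD27-CD11b+ replicate 1, 230 without CD27-CD11b+ replicate 2, 236 without CD27+CD11b- replicate 1, 296 without CD27+CD11b- replicate 2 and 367 after adding 32 to the linear values, and the share of calls that were higher, 66.1%, was 73.5% with arrays centred on their medians, 52.2% after a further quantile normalization, 43.6% and 45.9% without CD27+CD11b- replicate 1 and 2, and 48.8% and 56.1% without CD27-CD11b+ replicate 1 and 2.

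**Figure D2:**
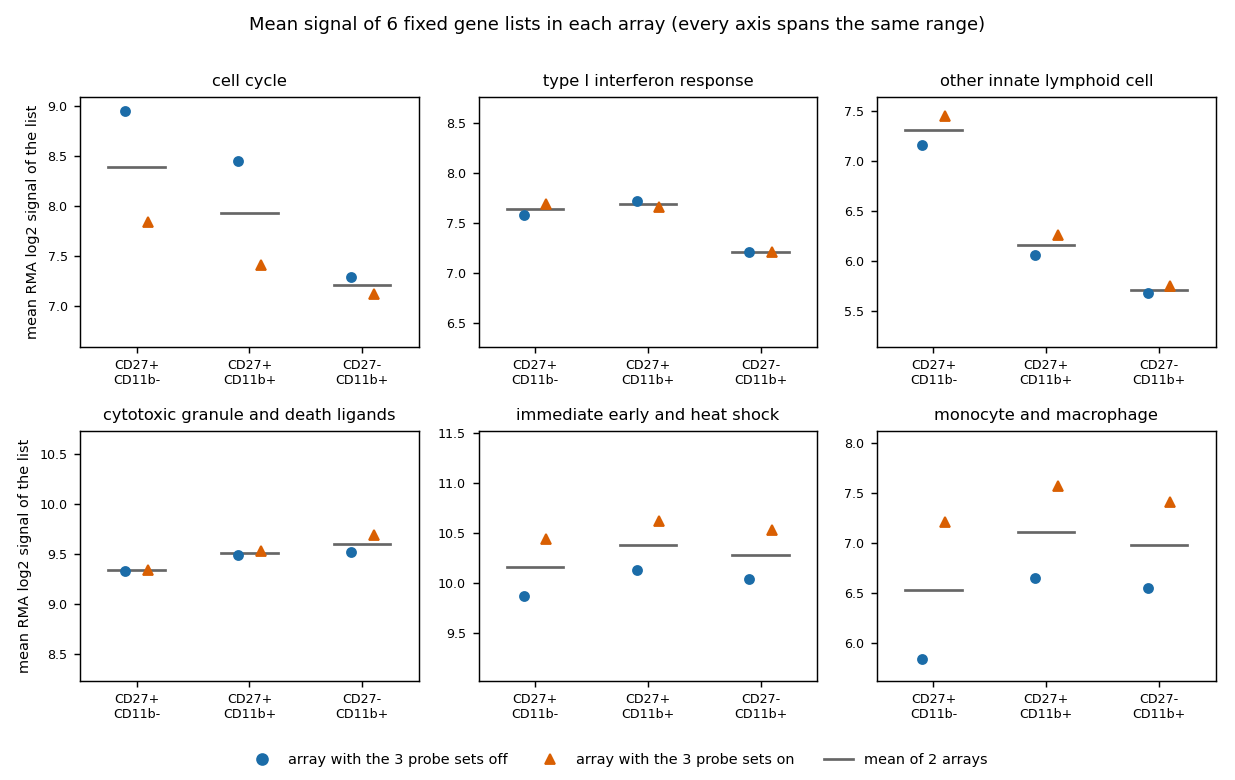
Mean log2 level of 6 gene lists (vertical axis) in the 3 subsets (horizontal axis), with 1 mark per array, circles for the off arrays and triangles for the on arrays and a line at the mean of 2 arrays. The monocyte and macrophage list spans 5.84 to 7.21 between the 2 CD27+CD11b- arrays, and the cell cycle list 7.84 to 8.95.

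The 2 steps of the order were then compared with each other. Of the 617 genes that differed between the outer subsets, 476 had the larger difference at the second step. Klrg1, Cma1 and Cmklr1 rose and Il7r, Cd160 and Acpp fell in both steps, 6 genes in all. All 22 genes of the first step and all 54 of the second were also called between the outer subsets, and 547 of the 617 were called in neither step. Kcnj8 was the only gene whose steps differed by the test of the difference itself (3.50, SE 0.28, adjusted p = 0.0314), at 6.16 ± 0.05, 6.60 ± 0.17 and 10.54 ± 0.16, and the blocked fit added Myb. The Kcnj8 mean in CD27+CD11b- lies near background, so its first step may be larger than the 0.44 measured and the difference of the steps smaller than 3.50. The count was 0 with 32 added, with every probe set tested and without any 1 of the 6 arrays. An F test over the 3 subsets passed 246 genes. Across genes, which are not independent replicates, the log2 differences of the steps correlated at 0.217. Both steps share the CD27+CD11b+ arrays, and 100 simulations of unchanged subsets gave a mean correlation of -0.499. The covariance was 0.0155 against a simulated -0.0199, a difference of 0.0355. Without CD27+CD11b+ replicate 1 the correlation was -0.0809 and without CD27+CD11b+ replicate 2 it was -0.189, where simulations with the remaining array gave -0.667 for each. The simulations held no on and off division, although their spreads included it. With all 6 arrays the division cancels from the differences, so the simulated covariance may be too negative. With 1 CD27+CD11b+ array left out the division enters both steps, which the simulations did not reproduce.

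**Figure D3:**
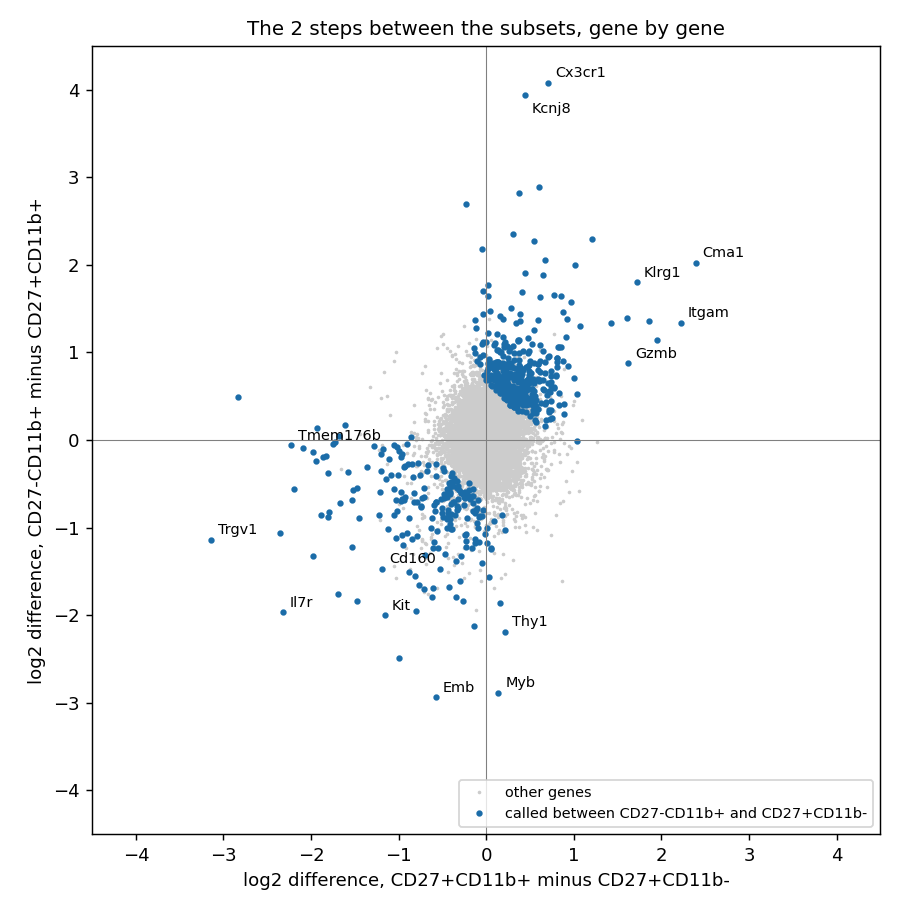
Log2 difference of CD27+CD11b+ from CD27+CD11b- (horizontal axis) against that of CD27-CD11b+ from CD27+CD11b+ (vertical axis), 1 point per gene, with the 617 genes called between the outer subsets in blue. Kcnj8 and Cx3cr1 stand high on the vertical axis at 3.94 and 4.08, and Il7r, with -2.32 and -1.96, lies low on both.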

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

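The fit with the on and off arrays as a block was the only alternative chosen after the results were seen. None of the 129 results of named genes turned direction under any of the alternatives run on them. For the block fits, the trend, 32 added and each array left out, this was fixed in advance. Blocks and a trend leave the differences as they are, and the arrays of called genes did not overlap. Only a further quantile normalization, centred arrays and the mean of a gene's probe sets could have turned a direction. Between 57 (32 added) and 129 (blocked fit, trend) kept their call in the fits with all arrays. The cause was not tested except where stated. The first, second and outer comparison called 58, 296 and 1480 genes in the blocked fit (from 22, 54 and 617), the F test 874 (from 246) and the test of the steps 2 (from 1). With 32 added the 5 counts were 0, 11, 367, 55 and 0. The first count was 11 with the mean of a gene's probe sets, 12 with every probe set tested and 12 with the 2 subsets alone, the second 31 with every probe set tested, and the outer one 374 at 2-fold, which by construction removes calls. Genes whose steps differ numbered 2 with dim genes left out, 2 after quantile normalization, 2 with a trend and 0 with every probe set tested.

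Leaving out 1 array gave 4 to 30, 6 to 53, 84 to 635, 53 to 237 and 0 to 0 genes for the same 5 counts, with a lone array assumed to vary like the others. The lowest outer count, 84, came without CD27-CD11b+ replicate 1. The correlation of the steps ranged from -0.189 to 0.245, turning negative at -0.0809 without CD27+CD11b+ replicate 1 and at -0.189 without CD27+CD11b+ replicate 2. A lone shared array by construction enlarges the negative term, and the covariance stayed above the simulated one by 0.0321 and 0.0197. Of the 10 lists called in the first comparison, the medians of 2 turned without CD27+CD11b- replicate 1. The cell cycle median became 0.087 (lowest of the 6 arrays left out -1.20) and the monocyte and macrophage median -0.051 (highest 1.499). The immediate early median fell to 0.0011 (highest 0.60) with its camera direction turned. All of these lists differed between the on and off arrays, and leaving out 1 array lets that division enter the median. The megakaryocyte median turned to -0.017 without CD27+CD11b+ replicate 2. Medians of uncalled lists turned as well, that of neutrophil markers to -0.21 without CD27+CD11b- replicate 1. Lists called ranged from 3 to 11, 5 to 10 and 7 to 11 in the 3 comparisons (from 10, 6 and 8). With an estimated correlation 0 lists were called in each comparison, in the main and in the blocked fit. The few residual degrees of freedom of that test could lose these calls without any correlation between genes.

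The replicate number as a block gave 19, 58, 760, 253 and 0 genes for the 5 counts. Only 2 numbers exist and the labels tie none to an animal or day, so the pairing is not established: deviations of same-numbered arrays correlated at 0.622 between CD27+CD11b- and CD27+CD11b+, and at -0.249 and -0.139 with CD27-CD11b+. With dim genes left out the median difference of all genes was 0.10 in the second and 0.11 in the outer comparison (0.02 and -0.01 with all genes in the same fit). Of the 617 outer calls, 84 were near background in both subsets. Calls near background in 1 subset only, such as Kcnj8 and Kit, are limited as well.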

Other observations

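Apart from the Spearman correlations of the macrophage genes, the tests in this part were chosen after the results were seen, as were the genes named here that lie outside the rule for named genes. The fit with the on and off arrays as a block called further genes between CD27-CD11b+ and CD27+CD11b- that did not pass in the fit without it. Its adjusted p-values may be too small, because the block was read from the same data. Fasl, the death ligand of the receptor Fas, went from 11.65 ± 0.47 to 13.03 ± 0.49 (SD, n = 2; difference 1.38, limma adjusted p = 0.0648 without and 0.00112 with the block). Tgfbr3, a co-receptor for transforming growth factor beta, differed by 1.42 (adjusted p = 0.128 and 0.00133). Xcl1, a chemokine that attracts cross-presenting dendritic cells, differed by -1.84 (adjusted p = 0.0518 and 0.00210), and Myc by -1.07 (adjusted p = 0.0798 and 0.00416). Ccna2, the S-phase and mitotic cyclin A, differed by -2.43 (adjusted p = 0.0760 and 6.95e-04).

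Trgv1, of an antigen receptor locus, was 9.81, 6.66 and 5.52 in CD27+CD11b-, CD27+CD11b+ and CD27-CD11b+ of these RAG-deficient mice, and Ighm was 10.98, 10.94 and 10.14. Cd3d, a signalling chain of CD3, was 7.92, 7.04 and 5.53. Cd3e, at 6.04, 6.28 and 6.41, Cd4, at 6.11, 5.97 and 5.80, and Cd8a, at 6.03, 5.91 and 5.77, were near background in every subset. Of all probe sets, 113 lay at least 2 log2 units below every other array in CD27-CD11b+ replicate 1 alone, 101 of them unnamed, while 0 did so in any other array, and St6galnac3 was the only called gene whose tested probe set was among them. A defect of that array was not tested.

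The 3 probe sets that were on in 1 array and off in the other array of every subset crossed the replicate numbers, as they were on in replicate 1 of CD27-CD11b+ and in replicate 2 of the other subsets. A candidate explanation is that CD27-CD11b+ replicate 1 shares its preparation with replicate 2 of the other subsets. Of 111 other probe sets with a gap of at least 1 log2 unit in every subset, 76 (68.5%) had the crossed direction, 35 followed the replicate number and 0 followed either remaining pattern. The sorting markers Itgam (6.37 and 5.88, 8.69 and 8.01, 9.93 and 9.44 in replicates 1 and 2 of CD27+CD11b-, CD27+CD11b+ and CD27-CD11b+) and Cd27 were higher in replicate 1 of every subset, and so followed the replicate number. The 3 probe sets have no gene name here. Whether arrays of the crossed direction share a preparation stays open, and no biological explanation was tested, since the division lies within subsets.

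Transcripts used as markers of other innate lymphoid cells were highest in CD27+CD11b-. A falling share of 1 such cell type as the only source was examined in Il7r, Tmem176a and Tmem176b, above background in every subset. From 1 source these genes would keep the same part of their excess in CD27+CD11b+. Il7r kept 17.6% and 13.8% in replicates 1 and 2 of CD27+CD11b+, and Tmem176b -3.01% and 5.76%. Tmem176a kept at most 2.36%, but its mean of 6.57 in CD27+CD11b+ lay just above the background level of 6.46. Il7r and Tmem176b thus kept different parts, which 1 source alone would not give. With 2 genes, 2 arrays and no error on the percentages, this cannot decide the question. Kit and Cxcr6 were near background in CD27-CD11b+, and Cxcr6 kept -10.4% in 1 array, so the percentages of these genes decide nothing. Such cells may still be the source of Cxcr6, Tmem176a and Tmem176b. That cannot be told apart, because 0 of the 4 measured list members that NK cells lack (Il17a, Il5, Il13 and Il1r1) lay above background in CD27+CD11b-, genes near background exclude nothing, and the NK1.1 gate would remove only those without NK1.1. Il7r, Kit and Cxcr6 are also in the cytokine receptor and homing lists of NK cell genes, and a difference between the NK subsets themselves stays open and untested.

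Monocyte and macrophage transcripts differed between the 2 arrays of every subset, with median gaps of 1.63, 1.01 and 0.95 log2 units between on and off arrays in CD27+CD11b-, CD27+CD11b+ and CD27-CD11b+, and 17 of 20 genes higher in the on array each time; C1qb, among the abundant macrophage transcripts, was 4.59, 6.50 and 6.09 in the off and 6.81, 7.44 and 7.81 in the on arrays. A lower share of NK cells would raise the transcripts of every other cell type alike. The 5 erythroid markers above background had a highest median gap of -0.43. The 14 monocyte and macrophage markers above background had gaps of 1.79, 1.17 and 1.06. This cannot decide the question, because the erythroid list holds Tfrc, which differed between these NK subsets. Neutrophil and dendritic cell markers, given below, also had gaps in the direction of the macrophage markers. RNA of 1 kind of macrophage in unequal amounts may be a source. Across the 20 genes the linear gaps of 2 subsets had Spearman correlations of 0.914, 0.908 and 0.788, the lowest short of the 0.8 set in advance. A linear gap also grows with the brightness of its gene, so a shared rise of any source would rank the genes much alike. This source therefore cannot be told apart from unequal kinds of cells, although the NK1.1 gate should exclude macrophages. The 7 neutrophil markers above background had gaps in the same direction (2.25, 1.30 and 0.78, the first 2 larger than those of the macrophage markers), as had the 8 dendritic cell markers above background (0.99, 0.59 and 0.97) and immediate early and heat shock genes (0.54, 0.40 and 0.44). The gaps lie within subsets, and no biological explanation was tested.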
